A study of Danio rerio with 12 samples.

How the data were processed

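RNA was extracted from whole 2-day-old zebrafish of a wild-type strain, and libraries were made with the TruSeq RNA Library Preparation Kit v2, per the labels' protocols. This kit does not mark the strand, so reads from a gene and from a gene that overlaps it on the other strand could not be told apart. The 12 libraries were grouped by the perturbation in the labels into control, miR-101a and miR-29a, with 4 libraries each. The labels name no mock-treated group and do not say how the microRNA was given. Nothing states that the replicates came from separate clutches or embryos, so p-values measure the spread between these samples, which may be technical.

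The authors deposited a table of gene counts and a table of RPKM values, both with 1 column per library. The counts are whole numbers of reads per gene and were not normalized, and the submitters' processing notes name bcl2fastq 1.8.4, STAR 2.4.1d, featureCounts 1.4.6-p4 and the genome build GRCz10, with no settings. Each deposited RPKM value was found to be a gene's count divided by a gene length and by a library total, but the totals were recycled down the genes, so that most values were divided by the total of another library. This was tested on the 7554 genes with at least 300 counts in every library. With recycled totals the gene length implied by the 12 values had a coefficient of variation under 1% in 7554 of the 7554 genes (at most 0.0254%), and with each library's own total in 0 (median 17.6%). Only 8.33% of values were divided by their own library's total, and the largest error from a wrong total was 1.53-fold. These RPKM-like values were therefore used only as an alternative, next to RPKM recomputed from the counts with each library's own total.

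Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept with filterByExpr (minimum count 10), which left 20872 of 32105 genes, and libraries were scaled by TMM, with factors of 0.729 for miR-29a replicate 3 and 0.963 to 1.11 for the others. A quasi-likelihood model with robust estimation was fitted to all 12 libraries, so that the 3 groups shared 1 estimate of the spread, and every gene was tested with glmQLFTest. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, with no minimum fold change. Log2 fold changes are given with their standard errors, and counts per library as CPM after TMM scaling. All adjusted p-values of genes are from this test unless another is named, and those of lists are from camera (limma 3.58.1). Total counts ran from 19804199 to 30383374 per library.

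The tests, the gene lists and the rule for naming genes were fixed before the data were examined. The rule named, for each comparison with control, the 10 largest rises and 10 largest falls among called genes with a mean of at least 1 CPM in the higher group, no overlap between the groups and a symbol that is not a clone name, and in the direct comparison 5 of each. It added up to 2 called members per direction of each list by smallest p, or the member with the smallest p where none was called, and a set of genes that were always included. Some of these are given only as counts in the text, and results for some genes and for a list are not reported here.

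The 30 lists hold reported targets of miR-29 and miR-101, matrix and chromatin genes, stress, immune and cell cycle pathways, markers of tissues and cell types, and genes of the segmentation stage. Each was tested with camera at a preset inter-gene correlation of 0.01, adjusted over the 30 lists of a comparison, and again with an estimated correlation and with fry. Gene symbols came from a table that pairs gene identifiers with symbols. Of the 32105 identifiers 26269 had a symbol, and the 5836 without one held 1.44% of counts. Of 792 list entries 748 were matched, 565 by their own symbol, 2 by an alias, 12 by a synonym and 169 by a symbol shared between the copies of a duplicated gene. 44 entries, the elastin gene elna among them, were not matched and are not analysed here. Since 1709 symbols belong to more than 1 measured identifier, the identifier stands beside such symbols. Close copies, such as members of the ponzr, crygm2d, gvin and fast myosin families, can share reads, and their single values are uncertain.

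The shared response of both treatments was measured as the overlap of calls and as the correlation and covariance of log2 fold changes across genes. It was set beside 10 draws of simulated unchanged groups that share a simulated control group, and repeated with the controls split 2 and 2 in all 6 ways. Alternatives were median-ratio scaling (RLE), DESeq2 1.42.0, no filter on low counts, a filter of 1 CPM in 4 libraries, the replicate number as a block, only the 8 libraries compared, glmTreat against a 1.2-fold minimum, limma on log2(RPKM + 0.5) of the deposited values, and leaving out each library. Alternatives added after seeing the data were the shared response and lists without miR-29a replicate 3, a correction for gene length through offsets from a smooth trend (span 0.3), limma on recomputed RPKM, the replicate block without miR-29a replicate 3, and 3 added gene lists. Tests of genes with sites for the microRNA seeds, and the rank of the seeds among all 7-mers, were planned and not run, since they need 3′ untranslated regions that were not available here.

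The procedure was tested on simulated counts of 20871 genes with 200 changed. For miR-101a against control it recovered 17% of genes changed 1.5-fold and 51% of those changed 2-fold, with 6 false calls among 20671 unchanged genes. For miR-29a against control the values were 15%, 62% and 7, and for the direct comparison 11%, 53% and 4. Every simulated library was drawn with the spread fitted to the real libraries, to which miR-29a replicate 3 contributed. The real spread was uneven between libraries, so these rates may not hold for the real data. Replicates were also compared pairwise with a chi-square test over genes with a summed count of at least 20. The closest pair, control replicates 2 and 4, had a chi-square of 1.63 per degree of freedom, so no pair was alike within sampling noise. Pairs with miR-29a replicate 3 had 167 to 202, and all others at most 13.3. Values of a library were compared with its group by Dixon's test at a critical value of 0.829 for 4 samples.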

Results

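Gene expression was measured by RNA sequencing in whole wild-type zebrafish (Danio rerio) at an age of 2 days. The 12 libraries formed 3 groups of 4. The control group had no perturbation, the miR-101a group had 2 ng of synthetic miR-101a and the miR-29a group had 2 ng of synthetic miR-29a. A microRNA is a short RNA that guides Argonaute proteins to messenger RNAs with matching sites, mostly in their 3′ untranslated regions, and lowers their level or translation. miR-29 is best known for targeting collagen genes and other genes of the extracellular matrix, and miR-101 for targeting EZH2, the methyltransferase of Polycomb repressive complex 2. The design implies a comparison of each microRNA with control and a direct comparison of the microRNAs with each other.

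Total gene counts were 24456059, 28449797, 29585294 and 26482186 in control replicates 1 to 4. They were 30383374, 19804199, 27385192 and 24782088 in the miR-101a replicates and 21370921, 23444179, 26519051 and 27553451 in the miR-29a replicates. Of 32105 genes in the table, 20872 had enough counts to be tested. The spread between replicates corresponded to a biological coefficient of variation of 21.7%, a value to which miR-29a replicate 3 contributed. In that library 14.6% of counts fell on genes of ribosomal proteins, against 7.57% to 8.08% in the other miR-29a libraries and 8.51% to 9.02% in control. Its 50 most abundant genes held 23.3% of its counts, against 16.6% to 17.4% in the rest of its group. Short genes were over-represented in it and long genes under-represented: its median deviation from its group was 0.88 on the log2 scale in the decile of genes with the shortest transcripts (median 786 bases) and -0.63 in the decile with the longest (median 6877 bases). Across genes, which are not independent replicates, Spearman's correlation of this deviation with gene length was -0.394, while in the other 11 libraries it lay between -0.158 and 0.211. For many of the results that moved when this library was left out, the values without it are given.

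**Figure D1:**
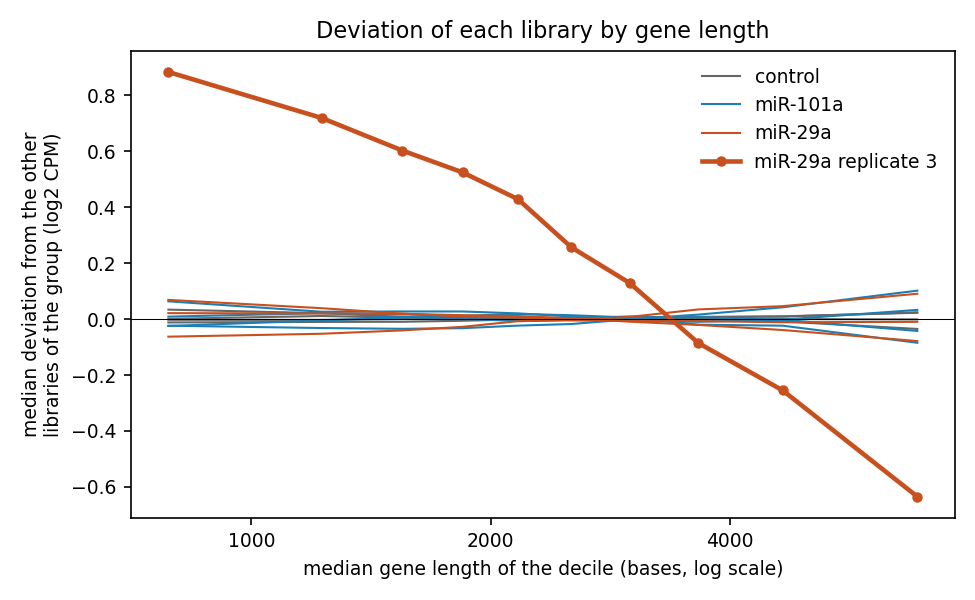
Median deviation of each library from the other libraries of its group (log2 CPM) for 10 classes of gene length, at the median length of each class in bases on a log scale. The line of miR-29a replicate 3 falls from 0.88 to -0.63, whereas the other 11 libraries stay close to 0.

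The first comparison asked which transcripts differed between embryos with synthetic miR-101a and untreated embryos. Enzymes of sterol synthesis were among the genes with the largest rises. FADS3 (ENSDARG00000019532), named for a fatty acid desaturase, rose by 4.02 ± 0.17 on the log2 scale (SE, n = 4 per group, adjusted p = 1.1e-07), from 3.89 ± 0.74 to 63.3 ± 10.8 CPM (counts scaled to library size, mean ± SD). The sterol synthesis enzymes MSMO1 (3.84 ± 0.20), CYP51A1 (3.32 ± 0.14) and LSS (3.30 ± 0.17) rose about as steeply, and so did isg15 (4.11 ± 0.40), a ubiquitin-like protein that interferon induces. The other genes with the largest rises were the trypsin-like protease prss59.1 (4.13 ± 0.46), arf4b (4.00 ± 0.33), the acetylcholine receptor subunit CHRNG (3.63 ± 0.14), snai3 (3.39 ± 0.32) and ms4a17a.4 (3.22 ± 0.46).

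The steepest falls were in leap2, ponzr4 (-4.64 ± 0.75), ponzr3 (-4.28 ± 0.79), gvin1l2 (-4.25 ± 0.47), DAO (ENSDARG00000035602, -4.23 ± 0.51), ACP5 (-3.85 ± 0.51), crygm2d14 (-3.72 ± 0.70), phka1b (-3.32 ± 0.36), crygm2d15 (-3.26 ± 0.69) and FKBP5 (-3.26 ± 0.51). leap2, which encodes an antimicrobial peptide, had 158 counts over the 4 control libraries and 3 over the miR-101a libraries, a ratio of 49.5 with an exact 95% counting interval of 16.6 to 242 that covers counting error only. DAO encodes D-amino acid oxidase, ACP5 the tartrate-resistant acid phosphatase of osteoclasts and FKBP5 a chaperone partner that glucocorticoids induce, while the crygm2d genes encode crystallins of the lens. As the rule for naming them required, the 4 miR-101a libraries lay on one side of the 4 control libraries in all of these genes. Without miR-101a replicate 1, DAO was at -4.88 and ACP5 at -4.55. The pairs ponzr3 and ponzr4, and crygm2d14 and crygm2d15, are similar copies whose reads may not have been assigned to the right member, and gvin1l2 has close copies too.

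In total 2451 genes were higher and 1454 lower with miR-101a, 18.7% of the genes tested, of which 62.8% were higher. A change of at least 2-fold was seen in 766 of the raised and 380 of the lowered genes. In 9141 genes (43.8%) the libraries of the 2 groups did not overlap at all, where chance gives 2.86%. These counts changed with the libraries in the fit: leaving out miR-29a replicate 3, which is not part of this comparison, gave 4989 higher and 5099 lower. Leaving out miR-101a replicate 1 gave 931 lower. The share of higher genes was 49.5% without miR-29a replicate 3, and 73.6% on RPKM values recomputed from the counts.

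Reported targets of miR-101 had a small median change. Of 32 measured, 5 fell and 1 rose, the same numbers when adjusted over the list alone. The median was -0.08 (camera adjusted p = 0.104, and 0.00358 downward by fry). Without miR-29a replicate 3, which is not part of this comparison, 11 fell and 5 rose (median -0.09, camera adjusted p = 0.0555). EZH2 (ENSDARG00000010571) fell by 0.63 on the log2 scale (SE 0.08, adjusted p = 2.0e-04), from 92.1 ± 2.1 to 59.4 ± 2.9 CPM, and LMNB1, a nuclear lamina protein, was at -0.74 ± 0.11. Of the 33 measured reported targets of miR-29, 8 fell and 1 rose in the same embryos, also when adjusted over the list alone (median -0.26, camera adjusted p = 0.0026, adjusted p = 0.357 with an estimated correlation). Among them loxl2a, a lysyl oxidase, was at -0.66 ± 0.09 and the thymine DNA glycosylase TDG (ENSDARG00000013004) at -0.49 ± 0.07. The member that rose was bbc3 (1.61 ± 0.21), a pro-apoptotic gene. Without miR-29a replicate 3, 17 of the reported miR-29 targets fell and 4 rose. IREB2, which controls translation by cellular iron, was at 0.05 ± 0.07 (adjusted p = 0.69), and COL1A2 (-0.19 ± 0.14) and COL4A1 (0.03 ± 0.12) were not called either. col1a1a was at -0.45 ± 0.14 (adjusted p = 0.04), a call that was lost whenever 1 of the 8 libraries compared was left out (adjusted p up to 0.112).

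The interferon response rose as a group. Of its 15 measured genes 9 rose and 0 fell, or 10 and 0 adjusted over the list alone, with a median of 1.04 (camera adjusted p = 1.4e-10, 0.00125 with an estimated correlation). irf9, a transcription factor of the interferon pathway, rose by 1.82 ± 0.11. HERPUD1 (1.13 ± 0.11) and DDIT3 (1.83 ± 0.28) were among 6 of 27 genes of the unfolded protein and heat shock response that rose, with 0 falling and the same counts over the list alone, but the list was not called (median 0.03, camera adjusted p = 0.274). Of 23 genes of innate immune cells 2 rose, the matrix protease MMP9 (1.72 ± 0.32) and MPEG1 (ENSDARG00000043093, 1.45 ± 0.30), with 0 falling, also over the list alone (median 0.24, camera adjusted p = 0.484). Without miR-29a replicate 3, 9 genes of the unfolded protein and heat shock list rose and 5 fell. In the innate immune list 7 then rose and 4 fell.

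Of 27 lens genes 13 fell and 0 rose in miR-101a embryos (17 and 0 adjusted over the list alone), with a median of -1.26 (camera adjusted p = 2.11e-09, adjusted p = 0.448 with an estimated correlation). In the liver and yolk syncytial layer list 8 of 31 fell and 0 rose (13 and 0 over the list alone), with a median of -0.39 (camera adjusted p = 2.39e-08, adjusted p = 0.407 with an estimated correlation), including the iron carrier transferrin, tfa (-1.88 ± 0.21), and the apolipoprotein apoea (-2.38 ± 0.27). Of 22 erythroid genes 9 fell and 2 rose (9 and 3 over the list alone), with a median of -0.53 (camera adjusted p = 0.00127, adjusted p = 0.562 with an estimated correlation). alas2, the first enzyme of heme synthesis in red cells, was among them (-1.14 ± 0.16). Pigment cell and neural crest genes had 6 of 23 lower and 0 higher (8 and 0 over the list alone; median -0.29, camera adjusted p = 1.33e-04, adjusted p = 0.21 with an estimated correlation), led by the melanosome protein pmela (-1.23 ± 0.11). In the endothelium list 5 of 28 fell and 0 rose, also over the list alone (median -0.18, camera adjusted p = 0.0341, adjusted p = 0.296 with an estimated correlation), with the VEGF receptor kdrl at -0.65 ± 0.11. Epidermal genes rose in 10 of 34 cases and fell in 0 (12 and 1 over the list alone), with a median of 0.30 (camera adjusted p = 0.00145, adjusted p = 0.562 with an estimated correlation). Those that rose included the plakophilin PKP1 (1.06 ± 0.07) and E-cadherin, cdh1 (0.75 ± 0.07). Without miR-29a replicate 3, the lower and higher genes numbered 20 and 0 for lens, 22 and 0 for liver and 13 and 4 for erythroid cells. They numbered 17 and 1 for pigment cells, 13 and 2 for endothelium and 3 and 21 for epidermis.

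Another 4 lists were called lower with miR-101a by camera, each with a call that was lost when some single library was left out. Without miR-29a replicate 3, their lower and higher genes numbered 11 and 5 for collagens and 7 and 3 for DNA methylation. They numbered 14 and 4 for retina and 18 and 5 for neural progenitors. Collagens had 6 of 30 lower and 0 higher (the same over the list alone; median -0.16, camera adjusted p = 0.03, adjusted p = 0.729 with an estimated correlation), including col7a1 (-0.77 ± 0.14) and col17a1a (-0.79 ± 0.14), the anchoring collagens of skin. The adjusted p was 0.0756 without miR-29a replicate 3, 0.0532 without control replicate 1 and 0.0524 without control replicate 3. DNA methylation and demethylation genes had 4 of 16 lower and 1 higher (5 and 2 over the list alone; median -0.20, adjusted p = 0.0474, adjusted p = 0.724 with an estimated correlation), with the methyltransferase dnmt3ba at -0.72 ± 0.11. The call was lost without miR-101a replicate 2 or 3 (0.0739 and 0.0832), without miR-29a replicate 1, 2 or 4 (0.0524, 0.0543 and 0.0546) and without control replicate 1 (0.0532). Retina and photoreceptor genes had 6 of 29 lower and 3 higher (7 and 3 over the list alone; median -0.37, adjusted p = 0.0474, adjusted p = 0.729 with an estimated correlation), with the arrestin sagb at -2.29 ± 0.27. That call was lost without miR-101a replicate 1 or 4 (0.0671 and 0.0719), without miR-29a replicate 2, 3 or 4 (0.0591, 0.0756 and 0.0685) and without control replicate 3 (0.0675). Neural progenitor genes had 5 of 30 lower and 1 higher (6 and 1 over the list alone; median -0.22, adjusted p = 0.0406, adjusted p = 0.729 with an estimated correlation, and 0.0524 without control replicate 3), with the RNA-binding protein MSI1 at -0.52 ± 0.08.

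The lists that follow were not called with miR-101a. Leaving out miR-29a replicate 3 gave more called genes in many of them, such as 2 higher and 14 lower for DNA replication and 4 and 17 for skeletal muscle. With all 12 libraries, their counts of higher and lower genes, over all genes and then adjusted over the list alone, were as follows. Basement membrane and elastic matrix had 6 and 0 of 25 (6 and 0; median 0.22, camera adjusted p = 0.307), where fibronectin FN1 (ENSDARG00000006526) was at 1.42 ± 0.27. Collagen processing had 2 and 4 of 23 (3 and 5; -0.08, 0.128), Polycomb complexes 0 and 2 of 21 (0 and 1; -0.14, 0.128) and iron handling 4 and 2 of 22 (6 and 2; 0.08, 0.614). DNA replication had 0 and 3 of 29 (0 and 2; -0.10, 0.0962), mitosis 0 and 2 of 27 (0 and 2; -0.02, 0.307) and the microRNA pathway 0 and 1 of 16 (0 and 1; -0.32, 0.0804, and without miR-29a replicate 3 0.0222, or 0.55 with an estimated correlation). Skeletal muscle had 2 and 4 of 40 (2 and 3; -0.22, 0.0637, and without that library 0.0132, or 0.699 with an estimated correlation), heart 2 and 2 of 20 (2 and 2; -0.27, 0.159) and cartilage and notochord 3 and 8 of 33 (3 and 10; -0.25, 0.0604). For neurons, 3 and 1 of 36 passed (3 and 1; median 0.11 but mean -0.0035, 0.852), for the hatching gland 1 and 0 of 10 (1 and 0; 0.28, 0.168) and for the early segmentation stage 4 and 3 of 17 (7 and 4; 0.42, 0.57). In the pancreas list 3 and 0 of 19 passed (3 and 0; median -0.03 but mean 0.306 and upward by camera, 0.57).

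The second comparison asked the same of embryos with synthetic miR-29a. Of 30 collagens 25 were lower, though the call of the list by camera was lost with an estimated correlation (adjusted p = 0.0606). col1a1a (ENSDARG00000012405), a chain of type I collagen, fell by 1.41 on the log2 scale (SE 0.14, n = 4 per group, adjusted p = 2.5e-05), from 2261 ± 91 to 851 ± 156 CPM. COL1A2, the other chain, was at -1.06 ± 0.14, the basement membrane collagen COL4A1 at -1.07 ± 0.12, the cartilage collagen COL2A1 (ENSDARG00000011407) at -1.31 ± 0.13 and COL11A1 at -1.97 ± 0.20. In the opposite direction fibronectin FN1 (ENSDARG00000006526) rose by 3.37 ± 0.29, from 148 ± 15 to 1530 ± 624 CPM, and the matrix protease MMP9 by 4.59 ± 0.35.

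Among the largest rises, il11b, an interleukin of the IL-6 family, had 0 counts in the 4 control libraries and 481 in the miR-29a libraries, so it was at least 177-fold higher, taking a floor of 3 counts over the control group (0.0275 CPM), a limit that covers counting error only. Its paralog il11a rose by 5.05 ± 0.57, the leptin gene lepb by 7.19 ± 1.15, the chemokines cxcl8a by 5.37 ± 1.06 and cxcl18b by 5.09 ± 0.66, the collagenase mmp13a by 5.29 ± 0.73 and the serum amyloid gene SAA2 by 5.41 ± 1.14. arf4b (5.54 ± 0.34), the cathepsin-like ctsll (5.19 ± 0.35) and ms4a17a.4 (5.10 ± 0.43) completed the list. With miR-29a replicate 3 left out, the limit for il11b was 118-fold and lepb stood at 6.07, cxcl8a at 3.90, cxcl18b at 4.101 and mmp13a at 4.50, and without miR-29a replicate 1 SAA2 stood at 4.82.

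The steepest falls included those of the opsin opn6a (-3.91 ± 0.32) and the eye transcription factor gene pax10 (-3.30 ± 0.27). gvin1l2 (-4.07 ± 0.46), ponzr4 (-3.90 ± 0.72) and ponzr3 (-3.60 ± 0.77) fell as they had with miR-101a. SOAT2 (-3.47 ± 0.50), which esterifies cholesterol, ccdc88aa (-3.33 ± 0.32), the clotting factor F7 (ENSDARG00000075827, -3.25 ± 0.43) and CYP4V2 (ENSDARG00000062132, -3.16 ± 0.31) followed. As the naming rule required, the 4 miR-29a libraries lay on one side of the 4 control libraries in each of these raised and lowered genes. Leaving out miR-29a replicate 3 gave -5.65 for ponzr4, -5.45 for ponzr3, -4.72 for gvin1l2 and -4.26 for SOAT2.

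In total 3564 genes were higher and 2481 lower with miR-29a (29.0% of those tested, 59.0% of them higher), of which 1277 and 847 changed at least 2-fold. The groups did not overlap in 6994 genes (33.5%), where chance gives 2.86%. When miR-29a replicate 3 was left out, 5442 were higher and 5653 lower. On the deposited RPKM-like values the share of higher genes was 45.1%, and the median of all genes shifted to -0.104.

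Of 33 reported miR-29 targets 21 fell and 1 rose (23 and 3 adjusted over the list alone), with a median of -0.81 (camera adjusted p = 2.18e-11, 0.0171 with an estimated correlation). The median was -0.51 without miR-29a replicate 3, with 25 lower and 3 higher (camera adjusted p = 2.09e-10). The adjusted p with an estimated correlation was then 0.105. This list shares 8 members with the collagens, 6 with the basement membrane list and 9 with the DNA methylation and demethylation list, so these lists are not independent. Outside the matrix the methyltransferases dnmt3ba (-1.04 ± 0.11) and DNMT3A (ENSDARG00000015566, -1.02 ± 0.28) and the PI3-kinase subunit PIK3R1 (-0.71 ± 0.07) fell, and bbc3 was the member that rose (1.86 ± 0.21). The methyltransferase DNMT3B (ENSDARG00000036791) overlapped with control, at 28.2 to 42.4 CPM with miR-29a and 36.9 to 40.2 CPM in control. IREB2, a reported target of miR-29 in fish, was at -0.14 ± 0.07 (adjusted p = 0.17), and at -0.18 and called without miR-29a replicate 3 (adjusted p = 0.0152). Reported miR-101 targets had 5 higher and 6 lower of 32, also over the list alone (median 0.01 but downward by camera, adjusted p = 0.495). Of these EZH2 was at -0.74 ± 0.08, and the prostaglandin synthase PTGS2 (ENSDARG00000010276) rose by 2.13 ± 0.26.

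Of 30 collagens 25 fell and 0 rose (26 and 0 adjusted over the list alone), with a median of -1.09 (camera adjusted p = 5.41e-24, adjusted p = 0.0606 with an estimated correlation). The median was -1.08 and 26 fell without miR-29a replicate 3 (camera adjusted p = 1.02e-15, adjusted p = 0.143 with an estimated correlation). col28a1a (-2.66 ± 0.24) had the smallest p-value among them. Basement membrane and elastic matrix genes went both ways, with 11 of 25 falling and 2 rising (13 and 2 over the list alone; median -0.50, camera adjusted p = 1.68e-04, adjusted p = 0.427 with an estimated correlation). The falls included col4a5 (-1.48 ± 0.11) and the rises were those of the fibronectin genes. With miR-29a replicate 3 left out the list was not called (median -0.34, adjusted p = 0.0744). In collagen processing 6 of 23 fell and 2 rose (6 and 4 over the list alone; median -0.18, camera adjusted p = 0.179), with the crosslinking enzyme LOXL2 at -1.07 ± 0.13 and the gelatinase MMP2 at 0.73 ± 0.07. The related loxl2a, also a reported miR-29 target, leaned upward, at 39.6 to 43.6 CPM with miR-29a and 33.0 to 38.9 CPM in control. Cartilage and notochord genes had 16 of 33 lower and 3 higher (17 and 5 over the list alone), with a median of -0.77 (camera adjusted p = 6.26e-06, adjusted p = 0.293 with an estimated correlation). The lower genes included a copy of the cartilage matrix gene MATN3 (ENSDARG00000069245, -1.89 ± 0.19). Its other copy (ENSDARG00000069265) leaned the other way, at 9.80 to 20.5 CPM with miR-29a and 6.92 to 12.8 CPM in control, ranges that overlap. DNA methylation and demethylation genes had 7 of 16 lower and 1 higher, also over the list alone (median -0.44, camera adjusted p = 0.00735, adjusted p = 0.415 with an estimated correlation). Of these 16 genes 9 are also on the list of reported miR-29 targets.

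**Figure D2:**
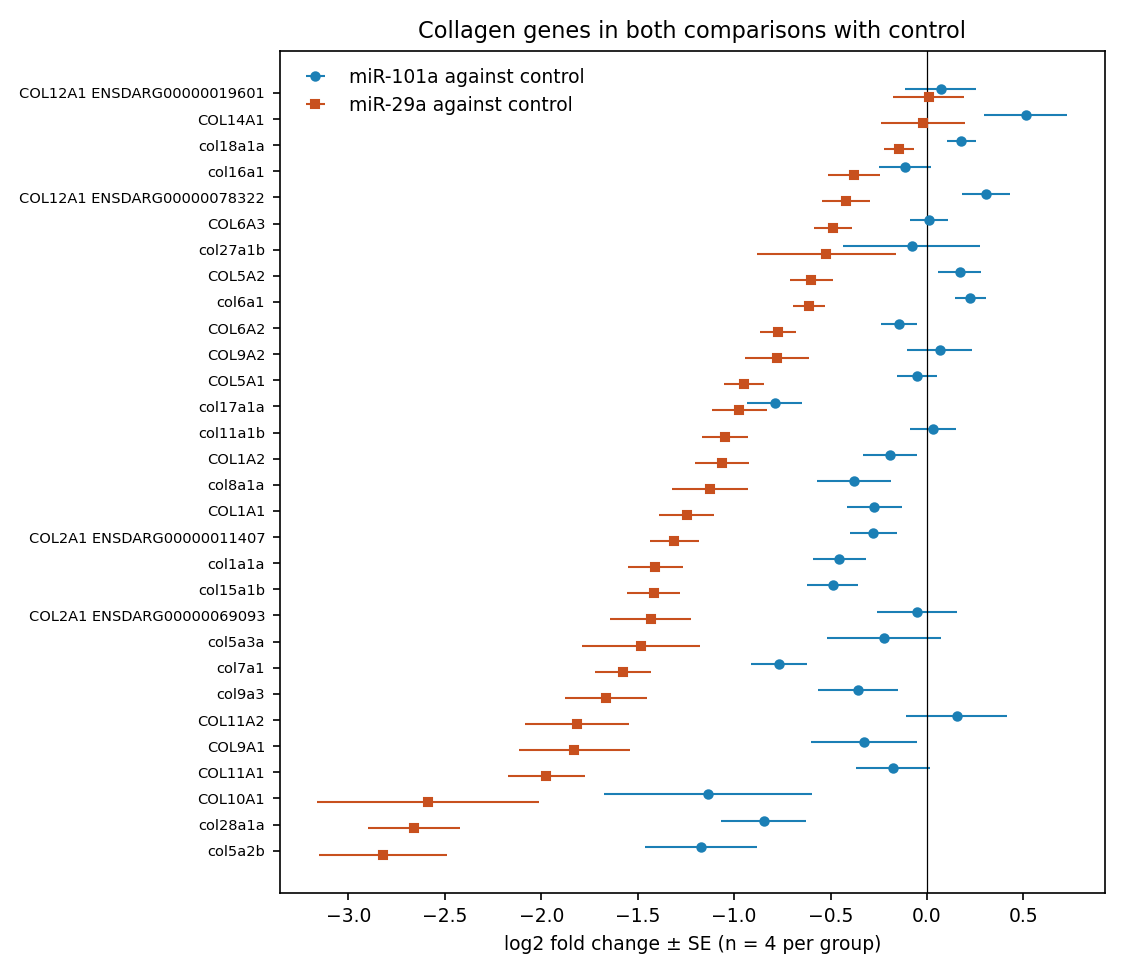
Log2 fold change ± SE (n = 4 per group) of each of the 30 measured collagens in miR-101a (blue circles) and miR-29a embryos (red squares) against control, ordered by the miR-29a value. With miR-29a 25 of the 30 passed as lower and 0 as higher, and with miR-101a 6 and 0 did.

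In the lens list 26 of 27 fell and 0 rose (27 and 0 over the list alone), with a median of -2.16 (camera adjusted p = 1.6e-15, adjusted p = 0.235 with an estimated correlation). In the retina and photoreceptor list 24 of 29 fell and 0 rose (27 and 0 over the list alone), with a median of -1.60 (camera adjusted p = 4.38e-15, adjusted p = 0.186 with an estimated correlation), among them the eye field gene rx1 (-1.69 ± 0.18). Of 20 heart genes 12 fell and 1 rose (16 and 1 over the list alone), with a median of -1.42 (camera adjusted p = 8.65e-08, adjusted p = 0.134 with an estimated correlation), including the myosin MYH7 (-2.36 ± 0.31) and the sodium-calcium exchanger SLC8A1 (ENSDARG00000013422, -1.61 ± 0.20). Skeletal muscle genes fell in 14 of 40 cases and rose in 2 (15 and 2 over the list alone), with a median of -0.62 (camera adjusted p = 5e-07, adjusted p = 0.304 with an estimated correlation). Their lead gene, the fast myosin myhz2 (-1.17 ± 0.13), has near-identical neighbours. In the 11 libraries without miR-29a replicate 3, 27 lens, 28 retina, 17 heart and 30 muscle genes fell, with medians of -2.48, -1.86, -1.72 and -0.99.

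Neuronal genes had 9 of 36 lower and 1 higher, also over the list alone (median -0.19, camera adjusted p = 0.0078, adjusted p = 0.304 with an estimated correlation), with the neurofilament nefla at -2.08 ± 0.28. Neural progenitor genes had 10 of 30 lower and 2 higher (11 and 3 over the list alone; median -0.24, camera adjusted p = 0.00451, adjusted p = 0.435 with an estimated correlation), with PAX6 (ENSDARG00000045936) at -1.32 ± 0.11. In the mitosis list 10 of 27 fell and 0 rose (11 and 0 over the list alone; median -0.29, camera adjusted p = 1.7e-04, adjusted p = 0.304 with an estimated correlation), led by the spindle motor kif11 (-0.68 ± 0.07). In DNA replication 11 of 29 fell and 0 rose (12 and 0 over the list alone; median -0.24, camera adjusted p = 0.00572, adjusted p = 0.584 with an estimated correlation), led by the helicase subunit MCM6 (ENSDARG00000057683, -0.48 ± 0.08). The numbers that fell without miR-29a replicate 3 were 21 for progenitors, 24 for mitosis and 22 for replication. Polycomb genes had 5 of 21 lower and 0 higher, also over the list alone (median -0.09, camera adjusted p = 0.0595, and without that library 0.00522, or 0.105 with an estimated correlation), with SUZ12 (ENSDARG00000070256) at -0.80 ± 0.08. Endothelial genes went both ways, 10 of 28 lower and 4 higher (10 and 5 over the list alone; median -0.33, camera adjusted p = 0.0282, adjusted p = 0.186 with an estimated correlation), with the transcription factor sox18 at -0.93 ± 0.12 and the scavenger receptor stab2 at 1.37 ± 0.16. Without replicate 3, 17 of the endothelial genes fell and 5 rose.

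Of 15 interferon response genes 11 rose and 0 fell (13 and 0 over the list alone), with a median of 2.03 (camera adjusted p = 1.04e-15, 2.75e-04 with an estimated correlation), including trim25 (2.09 ± 0.10) and irf9 (2.31 ± 0.11). In the unfolded protein and heat shock list 12 of 27 rose and 0 fell (13 and 0 over the list alone; median 0.24, camera adjusted p = 5.79e-05, adjusted p = 0.266 with an estimated correlation), with EDEM1, which acts in the disposal of misfolded glycoproteins, at 0.86 ± 0.08 and the chaperone HSPA8 (ENSDARG00000037403) at 2.01 ± 0.20. Hatching gland genes had 5 of 10 higher and 0 lower (6 and 0 over the list alone; median 0.62, camera adjusted p = 0.0135, adjusted p = 0.435 with an estimated correlation), with klf17 at 1.06 ± 0.16, and a median of 0.30 without miR-29a replicate 3. Epidermal genes had 12 of 34 higher and 2 lower (13 and 4 over the list alone; median 0.14, camera adjusted p = 0.0136, adjusted p = 0.467 with an estimated correlation), with PKP1 at 1.44 ± 0.07. Without replicate 3 the epidermal list had 14 higher and 13 lower and a median of -0.02, though camera still called it upward (adjusted p = 0.0293, or 0.382 with an estimated correlation).

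Another 8 lists were not called with miR-29a. Counts are again of higher and lower genes, then of those adjusted over the list alone. Iron handling had 9 and 4 of 22 (11 and 4; median 0.48, camera adjusted p = 0.0866, and without miR-29a replicate 3 0.0283, or 0.13 with an estimated correlation), with the ferritin fthl28 at 1.91 ± 0.19 and the heme oxygenase HMOX1 at 1.14 ± 0.16. Innate immune cells had 7 and 2 of 23 (7 and 3; median -0.22 but mean 0.71 and upward by camera, 0.495). The microRNA pathway had 0 and 0 of 16 (0 and 0; -0.36, 0.0953), erythroid cells 3 and 3 of 22 (3 and 3; 0.18, 0.879) and the liver and yolk syncytial layer 10 and 3 of 31 (14 and 3; 0.26, 0.178), where the complement gene c3a.1 was at 1.60 ± 0.12 and PROX1 at -1.52 ± 0.20. Without replicate 3 the liver list had 14 higher and 10 lower, with a median of -0.01. The pancreas list had 4 and 5 of 19 (4 and 8; -0.68, 0.0969, and without that library 0.0283, or 0.382 with an estimated correlation). Pigment cells and neural crest had 3 and 3 of 23 (3 and 3; median 0.13 but mean -0.03, 0.705), with the purine synthesis gene PAICS at 1.46 ± 0.18, and early segmentation stage genes 5 and 5 of 17 (6 and 6; 0.44, 0.56), with the homeobox genes cdx4 at 2.66 ± 0.21 and vox at 3.27 ± 0.26.

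**Figure D3:**
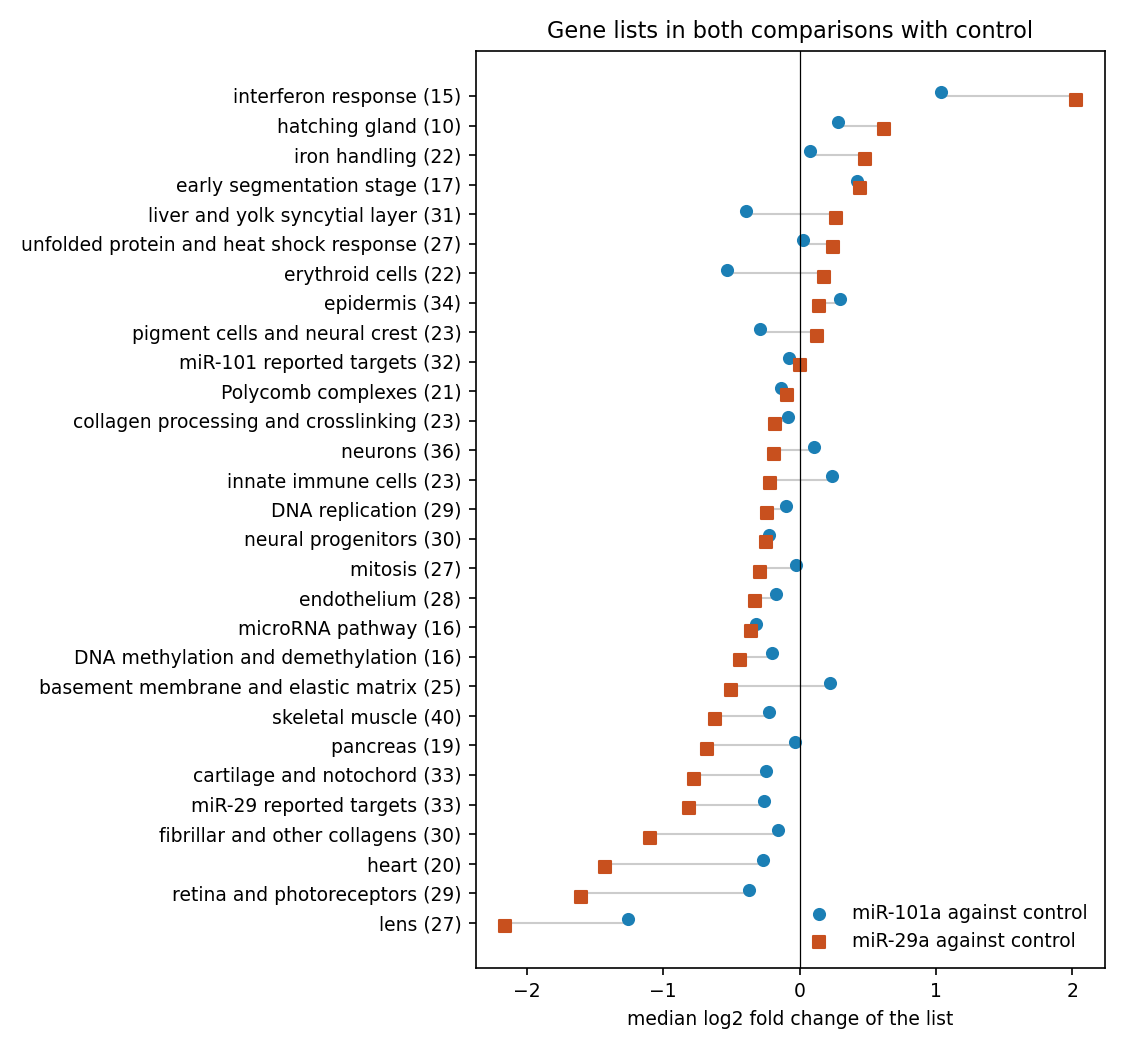
Median log2 fold change of gene lists against control with miR-101a (blue circles) and miR-29a (red squares), with the number of measured members in parentheses. The medians range from 2.03 (interferon response) to -2.16 (lens) with miR-29a and from 1.04 to -1.26 for the same lists with miR-101a.

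The third comparison set the microRNAs directly against each other at the same mass. By camera the lists of collagens, retina and heart were higher with miR-101a, and those of the liver and of the unfolded protein and heat shock response were higher with miR-29a. These calls were lost with an estimated correlation (adjusted p of 0.0513 to 0.244). COL11A1 was higher with miR-101a by 1.797 ± 0.199 on the log2 scale (SE, n = 4 per group, adjusted p = 1.7e-04), and col6a1 by 0.84 ± 0.08 (adjusted p = 9.7e-05). The largest excesses with miR-101a were those of the pituitary hormone prl (2.90 ± 0.55), the retinol dehydrogenase rdh1 (2.87 ± 0.34), the hemopexin gene hpxa (2.87 ± 0.35), ch25hl2 (2.67 ± 0.38) and the chloride channel clcn2c (2.64 ± 0.35). The largest excesses with miR-29a were those of ctsll (-3.75 ± 0.33), il11b (-3.60 ± 0.87), ACP5 (-3.50 ± 0.50), the complement gene c7b (-3.48 ± 0.59) and scpp5 (-3.45 ± 0.56), a gene of mineralized tissue. The collagenase mmp13a was at -3.43 ± 0.66.

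Some of these values leaned on single libraries. Without miR-29a replicate 2, prl was at 3.88. Without miR-101a replicate 1, ACP5 was at -4.19, scpp5 at -4.05, mmp13a at -4.08 and il11b at -5.11. Without miR-29a replicate 3, c7b was at -2.58, mmp13a at -2.63 and il11b at -2.73. The call of il11b (adjusted p = 0.022) was lost without miR-101a replicate 2, 3 or 4 (0.064, 0.0662 and 0.0661). In total 1927 genes were higher with miR-101a and 1803 with miR-29a (17.9% of those tested, 51.7% of them higher with miR-101a), 618 and 479 of them at least 2-fold. The groups did not overlap in 4926 genes (23.6%, where chance gives 2.86%). The called genes numbered 4657 and 4486 without miR-29a replicate 3, and 941 and 950 with only the 8 libraries compared. The share higher with miR-101a was 66.5% on the deposited RPKM-like values.

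Lists are given with the number of genes higher with miR-101a and the number higher with miR-29a, then the same adjusted over the list alone. Collagens had 24 and 0 of 30 (26 and 0; median 0.88, camera adjusted p = 2.17e-26, adjusted p = 0.0513 with an estimated correlation). Reported miR-29 targets had 15 and 2 of 33 (17 and 3; median 0.45, camera adjusted p = 1.76e-07, adjusted p = 0.0513 with an estimated correlation), with a median of 0.23 without miR-29a replicate 3. Reported miR-101 targets had 2 and 5 of 32 (2 and 5; -0.02, camera adjusted p = 0.445). EZH2 was at 0.11 ± 0.08 (adjusted p = 0.39, and 0.0201 without miR-29a replicate 3), and the 2 miR-101 targets with the smallest p-values among those higher with miR-29a were PTGS2 (ENSDARG00000010276, -1.63 ± 0.26) and LMNB1 (-0.52 ± 0.11). Basement membrane genes had 13 and 2 of 25 (15 and 2; median 0.55, camera adjusted p = 3.11e-09, adjusted p = 0.245 with an estimated correlation), and cartilage and notochord genes 12 and 3 of 33 (14 and 3; 0.38, 2.03e-04, adjusted p = 0.354 with an estimated correlation), with COL2A1 (ENSDARG00000011407) at 1.03 ± 0.13.

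Retina genes had 17 and 0 of 29 (20 and 0; median 1.302, camera adjusted p = 7.38e-15, adjusted p = 0.156 with an estimated correlation). Heart genes had 9 and 0 of 20 (10 and 0; 1.06, 5.68e-08, adjusted p = 0.123 with an estimated correlation), with SLC8A1 (ENSDARG00000013422) at 1.31 ± 0.20. Skeletal muscle had 9 and 0 of 40 (12 and 0; 0.42, 1.24e-05, adjusted p = 0.354 with an estimated correlation) and lens 5 and 0 of 27 (6 and 0; 0.89, 2.91e-05, adjusted p = 0.486 with an estimated correlation). Neurons had 11 and 1 of 36 (12 and 1; 0.15, 2.28e-04, adjusted p = 0.164 with an estimated correlation), with the GABA synthesis gene GAD1 (ENSDARG00000027419) at 0.61 ± 0.07 and the neurofilament nefma at 1.17 ± 0.14. Mitosis genes had 8 and 0 of 27 (9 and 0; 0.26, 2.03e-04, adjusted p = 0.354 with an estimated correlation), with the checkpoint kinase bub1 at 0.57 ± 0.10, and the pancreas 8 and 1 of 19 (9 and 3; 0.72, 0.00545, adjusted p = 0.489 with an estimated correlation), with the carboxypeptidase CPB1 at 1.74 ± 0.27. Without miR-29a replicate 3, 16 heart, 31 muscle, 18 lens and 25 mitosis genes were higher with miR-101a.

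Called in the other direction were the liver and yolk syncytial layer with 2 and 20 of 31 (2 and 21; median -0.73, camera adjusted p = 1.61e-14, adjusted p = 0.156 with an estimated correlation), led by c3a.1 (-1.77 ± 0.12) and tfa (-1.98 ± 0.21), and the unfolded protein and heat shock response with 0 and 9 of 27 (0 and 10; -0.32, 5.83e-05, adjusted p = 0.244 with an estimated correlation), with hsp70.1 at -1.80 ± 0.26. Interferon response genes had 0 and 7 of 15 (0 and 7; -0.78, 2.85e-04, adjusted p = 0.0513 with an estimated correlation), with trim25 at -1.06 ± 0.10. Erythroid genes had 0 and 7 of 22 (2 and 11; -0.54, 2.03e-04, adjusted p = 0.354 with an estimated correlation), with the master regulator gata1a at -1.38 ± 0.15, and pigment cell genes 1 and 7 of 23 (1 and 11; -0.43, 2.66e-04, adjusted p = 0.142 with an estimated correlation), with pmela at -1.55 ± 0.11 and the xanthine dehydrogenase XDH at -1.39 ± 0.16.

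Not called in the direct comparison were collagen processing with 6 and 5 of 23 (7 and 6; median 0.22, camera adjusted p = 0.924), DNA methylation with 3 and 1 of 16 (4 and 1; 0.17, 0.247), Polycomb complexes with 2 and 0 of 21 (1 and 0; 0.02, 0.467) and iron handling with 4 and 8 of 22 (5 and 11; -0.48, 0.0976). The same held for DNA replication with 3 and 0 of 29 (3 and 0; 0.08, 0.0976), innate immune cells with 4 and 4 of 23 (4 and 6; 0.04, 0.692), the microRNA pathway with 0 and 0 of 16 (0 and 0; 0.02, 0.851) and neural progenitors with 5 and 2 of 30 (5 and 2; 0.10, 0.2). It also held for the endothelium with 6 and 2 of 28 (6 and 2; 0.01, 0.723), the hatching gland with 0 and 4 of 10 (2 and 5; -0.36, 0.0994), the epidermis with 4 and 7 of 34 (4 and 7; 0.05, 0.859) and the early segmentation stage with 3 and 3 of 17 (3 and 3; -0.03, 0.851). Without miR-29a replicate 3, DNA replication (22 and 0, adjusted p = 3.06e-05), iron handling (0.0197) and neural progenitors (17 and 3, 0.00215) were called, but not with an estimated correlation (0.261, 0.138 and 0.257).

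Many genes changed the same way in both groups. In both treated groups 1650 genes were higher than in control, including the sterol enzymes MSMO1, CYP51A1 and LSS, and 784 were lower, including gvin1l2, ponzr3, ponzr4 and EZH2. Independent lists of these sizes would share 418.5 and 172.8 genes. In the opposite direction 111 genes were called, 46 of them higher with miR-101a and lower with miR-29a and 65 the reverse. Across the 20872 genes the log2 fold changes against control had a correlation of 0.673, a covariance of 0.263 and the same sign in 70.18%. Since both comparisons use the same controls, 3 unchanged groups that share a control group were simulated. All 12 libraries, the controls included, were drawn from the control means and the fitted spread, to which miR-29a replicate 3 contributed. On average over 10 draws this gave a correlation of 0.496, a covariance of 0.0383, the same sign in 66.7% and 0 genes called in both. With the controls split 2 and 2 between the comparisons, the covariance over 21463 genes was 0.263 to 0.272 and the correlation 0.585 to 0.619. The genes called in both then numbered 777 to 830 higher and 287 to 313 lower. Without miR-29a replicate 3, 3075 genes were higher and 3046 lower in both, with a covariance of 0.276.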

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

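The tests of gene length, of stage, of a wrong label by direction and of a partner for an exchange in miR-29a replicate 3 and the alternatives without that library were chosen after its deviation had been seen. The criteria of the other tests of these 3 patterns were written after the patterns had been seen and before the tests were run. Dixon's test was run on 345 sets of 4 libraries, of which it marks about 1 in 20 by chance, or 17.2, and it marked 37. Of the 34 marked values of named genes, 13 were in miR-29a replicate 3 and 8 in miR-101a replicate 1.

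miR-29a replicate 3 stood far from its group in its share of counts on the 50 most abundant genes (23.32%, others 16.63% to 17.44%), on ribosomal protein genes (14.62%, others 7.569% to 8.076%) and in its TMM factor (0.7294, others 1.085 to 1.111). A loss of reads from long genes fits: Spearman's correlation across genes of its deviation with gene length was -0.3943, against -0.1582 to 0.2114 in the other 11 libraries, which could come from partly degraded RNA or from the library preparation. Length may account for only part of the departure. The length correction gave 5096 called genes for miR-101a and 6835 for miR-29a against control, next to 3905 and 6045 without it. Leaving the library out gave 10088 and 11095. A few abundant genes did not account for the departure, because without the top 50 the deviations of this library still had an SD 3.645 times the largest of the other libraries. An exchange of labels was argued against, since it needs a partner and each control and miR-101a library lay with its own group (lowest median position 0.8727, with miR-29a at 0 and its own group at 1). For a single wrong label, the library was placed between control or miR-101a (0) and miR-29a (1), and over all separating genes it lay at medians of 0.6967 and 0.5719. Over the genes higher with miR-29a the medians were 0.9658 (bootstrap 95% interval 0.91 to 1.0262) and 0.8902 (0.7872 to 1.0009), which argues against a wrong label for these genes. Over the genes lower with miR-29a the medians as measured were 0.4562 (0.4191 to 0.4989) against control and 0.4735 (0.4337 to 0.516) against miR-101a. The interval against control lay wholly below the midpoint, nearer control, so these genes did not settle the question of a wrong label. Without the trend on gene length the medians by direction were 0.6153 to 0.8526, nearer miR-29a. A real difference of these embryos in condition, which was not tested, or in stage stays open: without the trend on gene length, 17 early segmentation stage genes had a median deviation of 0.1584 (bootstrap 95% interval -0.0841 to 0.4567), which spans the range of the other 11 libraries (-0.0676 to 0.0949), and 10 hatching gland genes 0.2804 (0.0393 to 0.5903, others -0.0988 to 0.1232).

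In the same library several named genes stood above the other 3: isg15 at 7.758 CPM (others 2.402 to 3.011), ponzr4 at 9.982 (0.569 to 1.205), ponzr3 at 19.29 (1.205 to 2.318), ACP5 at 148.3 (47.39 to 60.61), crygm2d14 at 10.81 (1.037 to 1.361) and crygm2d15 at 22.03 (1.349 to 4.86). FKBP5 was at 29.79 (5.637 to 8.556), tfa at 1502 (768.9 to 825.3), alas2 at 196.0 (111.2 to 124.3), lepb at 16.55 (1.897 to 4.115), cxcl18b at 68.06 (9.059 to 17.58) and c7b at 60.2 (10.19 to 15.89). DDIT3 was below the others, at 19.34 (54.9 to 59.77).

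miR-101a replicate 1 stood above its group in several named genes: il11b at 1.163 CPM (others 0.146 to 0.152), lepb at 1.634 (0.248 to 0.38), cxcl8a at 4.808 (1.437 to 1.633), mmp13a at 26.37 (7.252 to 9.139) and cxcl18b at 9.051 (3.948 to 4.461). It was also above in ACP5 at 14.11 (3.875 to 4.67) and HMOX1 at 37.34 (30.49 to 31.07), and below in ccdc88aa at 0.817 (2.084 to 2.131). ponzr4 was apart in miR-101a replicate 2 at 2.676 (1.54 to 1.645), and MSI1 at 97.1 (84.37 to 86.54) and prl at 13.45 (10.21 to 10.36) in miR-101a replicate 3.

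In control replicate 1, loxl2a was high at 38.86 CPM (others 32.98 to 33.87), and cdx4 at 0.711 (0.807 to 0.82) and GAD1 (ENSDARG00000027419) at 41.66 (44.35 to 44.76) were low. In control replicate 3, SOAT2 at 14.99 (13.62 to 13.76) and sox18 at 15.52 (14.18 to 14.33) were high, and dnmt3ba at 230.1 (255.8 to 260.8) and opn6a at 1.86 (2.309 to 2.389) were low. myhz2 was low in miR-29a replicate 1 at 643.7 (859.7 to 897.4), and col6a1 at 105.6 (81.88 to 85.75) and nefma at 33.9 (22.25 to 22.91) were high in miR-29a replicate 2.

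A second pattern was the large number of genes that changed the same way with both microRNAs, 1650 up and 784 down. Shared control libraries were argued against as its whole source, because with separate controls the lowest covariance of the fold changes was 0.2633, next to 0.2634 with shared controls and 0.0383 for simulated unchanged groups. The covariances rest on unlike sets of genes, 21463 with separate controls and 20872 with shared ones, so their closeness does not show that sharing added nothing. The counts of genes changed the same way did fall with separate controls, to 777 to 830 up and 287 to 313 down, where each comparison had 2 control libraries. A response to handling or to any synthetic RNA, rather than to the sequence of either microRNA, could give such genes too. It cannot be told apart from a shared effect of the microRNAs, since the design has 0 mock-treated libraries. That both microRNAs act on overlapping sets of targets is a hypothesis not tested here.

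The third pattern was the fall of collagen transcripts with miR-29a. Loss of reads from long genes in replicate 3 was argued against, because without that library the median of the collagens was -1.0812, next to -1.0943 with it, and the list stayed called by camera, though with an estimated correlation it was called in neither case (adjusted p = 0.143 and 0.0606). A lower share of cartilage and notochord cells might lower them as well. The 27 measured genes of those tissues that are not collagens had a median of -0.2851 without replicate 3, with a bootstrap 95% interval of -1.0749 to -0.1974 that spans -0.5406 (0.5 times the collagen median), so this explanation and repression by miR-29a cannot be told apart. Repression by miR-29a stays a hypothesis, since sites of the microRNA were not examined.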

How the results depend on the processing

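The alternatives without miR-29a replicate 3 for the lists and the shared response, the correction for gene length, the recomputed RPKM values and the block without replicate 3 were chosen after seeing the data, and the rest were planned. No direction of a named gene or list that was called became a call in the other direction under any alternative run (0 reversed). Of 338 results for named genes 311 were called, and 284 of these kept the call without each single library. The called named genes that lost it numbered 1 with DESeq2, 2 with RLE factors, 0 with the CPM filter, 8 without a filter, 8 with the block, 21 with only the 8 libraries compared, 44 with glmTreat, 5 with the length correction, 23 with recomputed RPKM and 91 with the deposited RPKM-like values. Of 90 list results 48 were called, and the calls lost numbered 2 with RLE factors, 45 with an estimated correlation, 5 with fry, 3 with the length correction, 0 with the block and 5 with the block without replicate 3. Lists called with the preset correlation numbered 13, 19 and 16 in the order miR-101a, miR-29a and direct comparison, and 1, 2 and 0 with an estimated one.

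Counts moved by more than 1.5 times were as follows, where a minimum fold lowers counts by construction and the other causes were not tested. With only the 8 libraries compared, miR-101a had 5339 higher and 4716 lower and the direct comparison 941 and 950. With a 1.2-fold minimum, miR-101a had 1424 and 638, miR-29a 1384 lower and the direct comparison 986 and 916. On the deposited RPKM-like values they were 808 and 527, 1285 and 1562, and 931 and 469. With the length correction, miR-101a had 2224 lower. With the controls split, 777, 830, 779, 795, 783 or 785 genes were higher in both treatments and 290, 313, 287, 300, 305 or 298 lower. Leaving out each library gave 1738 to 4989 higher and 931 to 5099 lower with miR-101a, 2826 to 5442 and 1877 to 5653 with miR-29a, and 1316 to 4657 and 1221 to 4486 in the direct comparison. The highest values came without miR-29a replicate 3, and with it kept the highest were 2475, 1442, 3618, 2307, 1824 and 2005. The shared response without it was 3075 and 3046, and lists called ran from 10 to 15, 19 to 22 and 16 to 19.

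By the criterion that every correlation exceed 0.1, replicate numbers did not pair the samples, although a weak sign of pairing remains: same-numbered libraries of different groups had correlations of deviations from -0.195 to 0.391, 7 of 12 above 0.1, and in 7 of 12 the own number correlated best (mean 0.134, other numbers -0.0397). In each group replicate 3 also had the lowest correlation of deviation with gene length. It was -0.1582 with miR-101a, -0.3943 with miR-29a and -0.0787 in control. The replicate block gave 2311 and 1357 with miR-101a, 3339 and 2512 with miR-29a and 1876 and 1619 in the direct comparison, and without miR-29a replicate 3 it gave 5177 and 5404, 5358 and 5609, and 4461 and 4460. The planned tests of genes with seed sites, with their alternatives, and of the rank of the seeds were not run. In simulated counts, drawn with the same fitted spread in every library, 11% to 17% of 1.5-fold changes were recovered.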

Other observations

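The cholesterol, lysosome and glucocorticoid lists in this part were chosen after genes of each had been seen among the largest changes, so their tests were run again without those genes. Genes of cholesterol synthesis and uptake rose nearly as a whole in both treatments. Of 27 measured, 25 rose and 0 fell with miR-101a (median 1.85) and 24 rose and 1 fell with miR-29a (median 1.83). The LDL receptor gene ldlra rose by 2.57 ± 0.24 with miR-101a and 2.56 ± 0.24 with miR-29a (SE, n = 4 per group), and insig1, which restrains the pathway, by 1.92 ± 0.10 and 1.93 ± 0.10. Without the genes first seen, 21 of 22 rose with miR-101a (median 1.79, camera adjusted p = 4.16e-05 with an estimated correlation) and 20 with miR-29a (median 1.6343, adjusted p = 1.3e-04). The direct comparison did not call the list (median 0.17, adjusted p = 0.0857), with 5 genes higher with miR-101a and 1 with miR-29a, or 10 and 3 without miR-29a replicate 3. It is a hypothesis that a common regulator of the pathway was more active, consistent with that rise of the rest of the list.

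Lysosomal genes rose too. Of 47 measured, 29 rose and 0 fell with miR-101a (median 0.52) and 35 rose and 1 fell with miR-29a (median 0.83), among them the protease CTSD (0.79 ± 0.14 and 1.76 ± 0.14). Without the genes first seen, the median of the other 43 was 0.4975 with miR-101a (adjusted p = 0.00629 with an estimated correlation) and 0.79 with miR-29a (adjusted p = 8.29e-04). In the direct comparison 1 was higher with miR-101a and 18 with miR-29a (median -0.23, camera adjusted p = 2.75e-07, adjusted p = 0.0829 with an estimated correlation). When miR-29a replicate 3 was left out, these were 6 and 23 (adjusted p = 0.22 with an estimated correlation).

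FKBP5 and KLF9, which glucocorticoids induce, fell steeply in both treatments, KLF9 by 2.03 on the log2 scale with miR-101a (SE 0.17) and by 2.98 with miR-29a (SE 0.19). The other 22 measured genes of the glucocorticoid-responsive list went both ways. With miR-101a 4 rose and 5 fell (median -0.22, camera adjusted p = 0.0587), and with miR-29a 4 rose and 7 fell (median -0.068, adjusted p = 0.0556). When miR-29a replicate 3 was left out, 7 rose and 10 fell in each. The criterion first written for this list took a median of the rest above -0.2 as speaking against a fall of the group, which the miR-29a median meets. It was set aside after the values were seen, because members went both ways, and the result is left undecided.

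Chance assignment of libraries was examined by refitting every split of the 8 libraries of a comparison into 4 and 4, with the other 4 libraries kept in the fit. In each of the 3 comparisons 1 of the 35 splits, the real one, gave as many called genes. The real splits called 3905 genes for miR-101a against control, 6045 for miR-29a against control and 3730 in the direct comparison. The highest of the other splits called 0. Each other split put libraries of both groups on each side, which adds the difference between the groups to the spread within a side. Its low count was therefore largely built in. A share of 1 in 35 is also the lowest that this test can reach. It cannot separate the treatment from any other difference between the groups.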
